A study of Mus musculus with 4 samples.

How the data were processed

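Visium spatial gene expression was measured on formalin-fixed, paraffin-embedded mouse brain sections of 5 µm, 2 control and 2 rNLS8, 1 section per sample. Per the labels, the genome build was mm10, and the header of the deposited matrices names Space Ranger 2.1.0. The probe set, its version, the slides, the sequencing runs and whether tissue detection was manual are not given in the sources used here. The labels give sex as female for replicate 1 and male for replicate 2 of each group.

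The deposited matrices hold raw UMI counts per gene and spot under tissue, without normalization. The deposited spatial tables hold a score, Moran's I per gene within a section, with its p-value and adjusted p-value per the file headers, and a signal, the mean count per spot after the authors scaled spots to the median total. The other deposited files hold spot barcodes, gene identifiers and symbols, and the array position of each spot with a mark for spots under tissue. The deposited p-values, the scaled signal, the images and their scale factors were not used, and distances were taken on the array grid.

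Of the 4992 spots on the array, 3962, 3343, 3033 and 2656 lay under tissue in control replicates 1 and 2 and rNLS8 replicates 1 and 2, and spots with at least 500 UMI were kept, which left out 152, 37, 2 and 1. The files list 19465 genes, of which 15084, 15648, 15741 and 15435 had a UMI, and the 10 most abundant genes took 4.47%, 4.04%, 4.10% and 4.13% of UMI. Xist is not among the listed genes. Over genes with at least 20 counts, the chi-square per degree of freedom of the counts of a pair of sections was 46.3 in control and 18.5 in rNLS8, so spread between sections exceeded counting error. Counting intervals and floors cover counting error only, and a count of 0 was read as up to 3 counts of the section's total. Bootstrap intervals of list medians resample the genes of the list as if independent, and do not cover spread between sections.

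Regions came from clustering the kept spots of the 4 sections together in scanpy 1.11.5 with leidenalg 0.10.2. Counts were scaled to 10000 per spot and log-transformed, 2000 variable genes were taken without the lists of response genes, each gene was centred within its section, and 30 principal components, 15 nearest neighbours and Leiden resolution 1 were used. Clusters were named by their leading genes and by region markers, with at least 3 detected markers. Cluster 6 was kept with the cortex although its leading genes hold no cortical marker and include Pvalb, a marker on the midbrain list. Over whole marker lists, its highest mean log2 lead over the clusters' mean was for cortex of all layers (0.52). The lead for midbrain and brainstem was 0.1. The rule set beforehand counts as cortical only clusters whose leading genes hold cortical layer markers, so keeping cluster 6 departs from it. Clusters 4, 11, 16 and 17 stayed unnamed. Low-count clusters at the section edge were set apart as a rim, which the whole-section sums include. Septum and ependyma had fewer than 50 spots in at least 1 section and were not tested as regions. This minimum was not applied to the comparison of layers, where the deep-layer cluster held 42 and 29 spots in the rNLS8 sections.

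UMI were summed per section and region, since spots of a section are not replicates. edgeR 4.0.16 (R 4.3.3) fitted quasi-likelihood models after trimmed-mean normalization and its default filter on low counts, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The comparisons were rNLS8 against control in whole sections, in the cortex and in each other named region, and the differences of that effect between cortical and all other spots and between the upper-layer and the deep-layer cluster, fitted on 8 sums with section as a block. The 31 gene lists were tested with camera at a preset correlation of 0.01 and with an estimated correlation, and with fry (limma 3.58.1), each adjusted over the lists. Camera compares a list with the other genes, while fry tests whether its genes move, on balance, 1 way. Some lists share members, so their results are not independent. Moran's I was compared with limma with a trend by mean count, over genes with counts in at least 10% of spots in each section. That trend enters the variance and does not adjust the score for a gene's level. Shares of spots were compared by an exact two-sided permutation test with scipy 1.17.1, whose smallest p here is 0.333. For correlations between neighbouring spots, cortical spots were thinned to 3000 UMI and compared with the mean of their neighbours on the array, up to 6 and at least 3. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.

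The tests, the gene lists, the region markers, the clustering settings and the rule for naming genes were set before the data were examined. The rule takes, per main comparison, the 10 genes with the largest rise and the 10 with the largest fall among those with an adjusted p under 0.05, a mean of at least 5 CPM in the higher group and groups that do not overlap, or the 5 with the smallest p in a direction where fewer than 5 pass. It adds up to 4 members of each list with the smallest p, the 5 largest changes per direction for interactions and for Moran's I, and always Tardbp, Trem2, Lgals3, Gfap, Aif1 and P2ry12. Other genes named, such as the remaining called members of a list and the genes of the other regions, were chosen after their values were seen. Genes with near-identical copies are given as uncertain.

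The alternatives set at the same time were DESeq2 1.42.0 and its size factors in edgeR, no filter or at least 50 counts in every sum, leaving out each section, all spots in tissue, sums thinned to the smallest total, spots matched by region, a replicate block, Leiden resolutions 0.5 and 2.0, clustering without centring, and Moran's I over genes in 1% or 50% of spots. Alternatives chosen after seeing the data were a replicate block with crossed numbers, the cortex without cluster 6 (also against all other spots) or as cluster 3 or cluster 7 alone, the cortex without spots next to meninges, the fits without the rim, and deep layers as all other cortical clusters. The list tests in the striatum and on the difference between cortex and other spots were also added then. Genes with 1 to 3 UMI in a group are given as the ratio of CPM from counts pooled over its 2 sections, with an exact 95% counting interval that covers counting alone.

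The pipeline was tested on simulated data drawn at the depth and spread of these sections, with 200 changed genes. In the cortex edgeR recovered 65% of genes with a simulated change of 2-fold and 97% with one of 4-fold, with 25 calls among the unchanged genes. In whole sections it recovered 48% and 98%, with 7 calls among the unchanged genes. For the difference between cortex and other spots it recovered 89% and 100%, and for upper against deep layers 42% and 78%. Camera with the preset correlation recovered the simulated list in whole sections and in the cortex, and camera with an estimated correlation recovered it in neither. The fry test recovered it in the cortex and not in whole sections. Genes of the simulated lists were drawn independently, whereas the interferon list had an estimated correlation of 0.66 in the cortex and 0.70 in whole sections. The simulation therefore does not show how camera with the preset correlation behaves on lists whose genes move together.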

Results

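Gene expression was mapped across 4 mouse brain sections, 2 labelled control and 2 labelled rNLS8, with a capture array that assigns each RNA count to a spot of tissue. In rNLS8 mice, withdrawal of doxycycline from the diet switches on a human TDP-43 transgene in neurons, and the protein, which lacks a working nuclear import signal, gathers in the cytoplasm as it does in amyotrophic lateral sclerosis. Per the labels, the brains were taken 3 weeks after that withdrawal, at 11 weeks of age, and cut at 5 µm. The series title names microglia, dendrites and the excitability of the cortex, so the cortex was compared on its own besides the whole section. The labels do not state in words that each section came from a separate animal, but give a different sex to the 2 sections of each group. Y-linked counts bear this out for control (0 and 107.3 CPM) but not for rNLS8 (136.7 and 139.1 CPM). Separate animals are thus not established for rNLS8, and the p-values measure only the spread between these sections.

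Control replicate 1 held 19064969 unique molecular identifiers (UMI, a tag that marks each captured molecule) and control replicate 2 held 23869254. rNLS8 replicate 1 held 28056089 UMI and rNLS8 replicate 2 held 17627577. The median spot held 5364, 6098, 9776 and 6316 UMI in that order, from 2688, 3083, 4118 and 3212 genes. Levels are in CPM, counts of a gene scaled to a common library total by the trimmed-mean method, with n = 2 sections per group throughout. Folds are log2 fold changes of rNLS8 over control, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. For edgeR fits, the standard error (SE) given is the size of the fold over the square root of the test's F value. It is derived from the test, and with so few sections a fold of many SE need not pass.

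**Figure D1:**
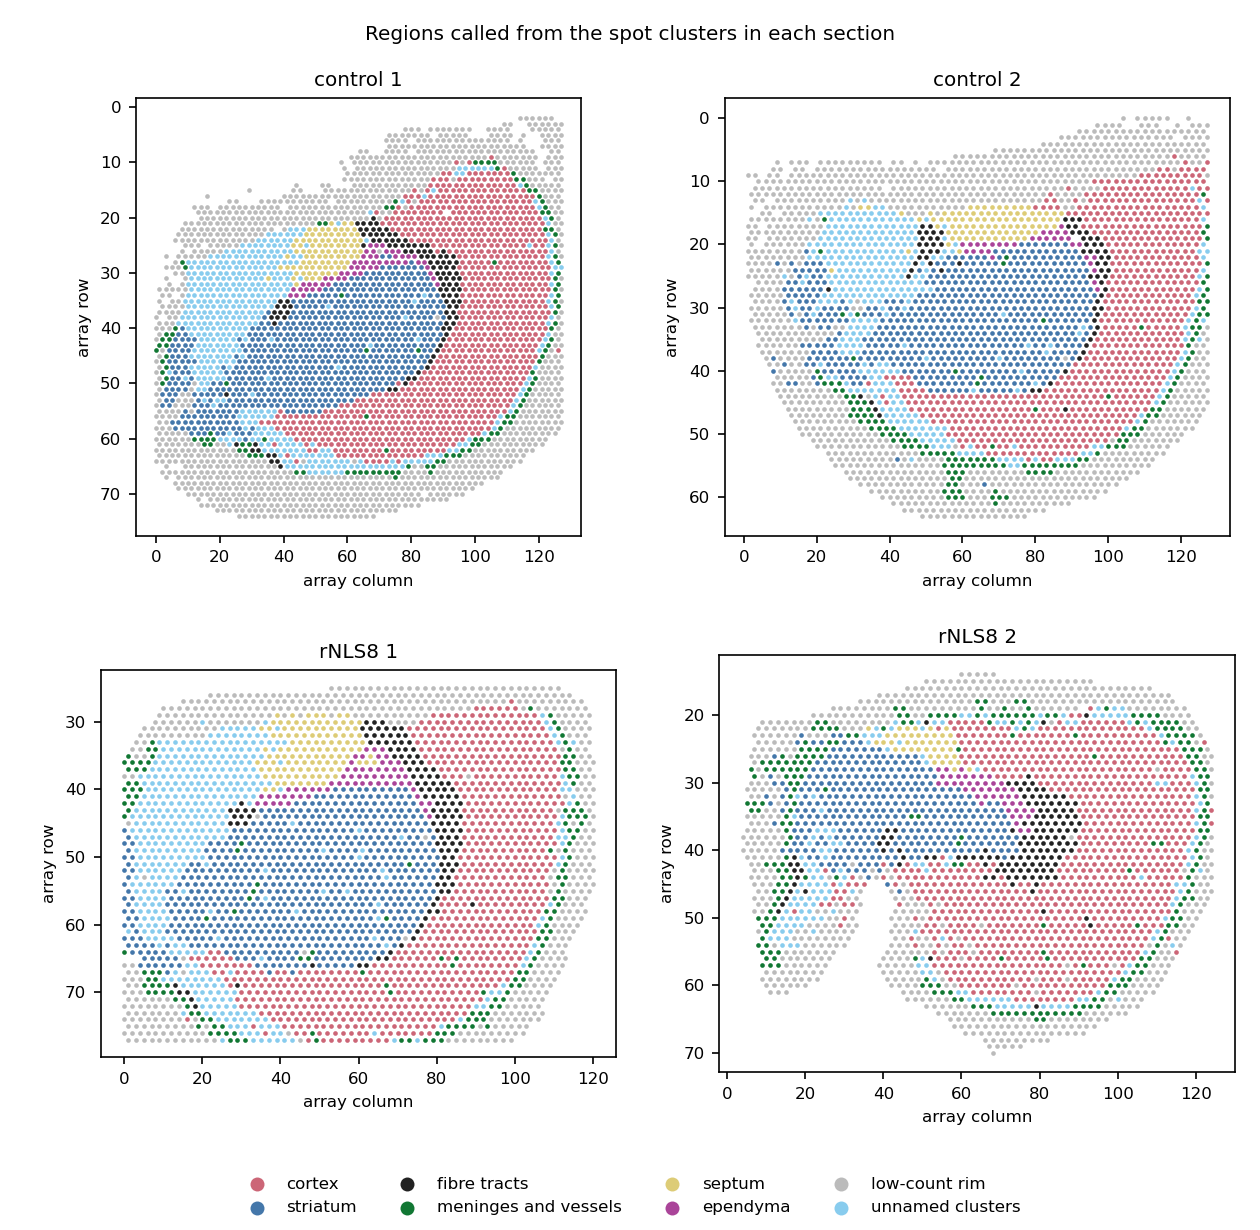
Regions of the 4 sections, drawn by array column and row, with 1 point per kept spot coloured by its region. Cortical clusters cover 26.3% and 23.2% of kept spots in the control sections and 28.3% and 36.1% in the rNLS8 sections.

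In whole sections, the 26 measured interferon-response genes, which cells switch on against viruses, had higher values in rNLS8, with a median log2 fold change of 2.00. Among them Bst2 stood at 9.94 ± 3.17 CPM (SD, n = 2) in control and 80 ± 24.6 CPM in rNLS8, and Usp18, which limits interferon signalling, at 2.65 ± 0.0294 and 19.6 ± 6.32 CPM. B2m, the light chain of class I antigen-presenting molecules, was at 55.5 ± 18.2 CPM in control and 366 ± 98.5 CPM in rNLS8, and Gfap, the filament protein of astrocytes, at 175 ± 11.0 and 663 ± 353 CPM. Lower values in rNLS8 included Prkcb, a protein kinase C, at 809 ± 74.8 CPM in control and 286 ± 36.9 CPM in rNLS8, and Camkk2, a calcium-dependent kinase, at 410 ± 10.5 and 148 ± 13.6 CPM.

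No single gene passed in whole sections. The edgeR quasi-likelihood test called 0 of 13444 genes, 2093 had an unadjusted p under 0.05, and DESeq2 called 529. The smallest adjusted p was 0.0966, shared by Ccl5 (1 UMI in control and 379 in rNLS8, a ratio of 356 with a 95% counting interval of 63.4 to 14080), Tardbp (at least 47.6-fold higher against a floor of 3 counts per section, since both control sections held 0 UMI), Pdrg1 (1.62, SE 0.145) and Igfn1 (-2.48, SE 0.197). It was 0.122 for Bst2 (3.00, SE 0.315), Usp18 (2.88, SE 0.311), B2m (2.72, SE 0.300), Cxcl10 (5.98, SE 0.675), Camkk2 (-1.47, SE 0.144), Tmem200b (-1.43, SE 0.147), Prkcb (-1.50, SE 0.168) and Muc3a (-1.87, SE 0.211), and 0.169 for Gfap (1.92, SE 0.365). P2ry12, a marker of resting microglia, stood at 0.19 and Lgals3, a lectin of phagocytes, at 0.47. The count of called genes was 2 without control replicate 1, 1839 without control replicate 2, 207 without rNLS8 replicate 1 and 37 without rNLS8 replicate 2. In 7011 genes (52.1%) the rNLS8 sections did not overlap the control sections, where chance gives 33.3%.

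Of the 31 gene lists, 14 were called in whole sections by the camera test with a preset correlation, 10 higher and 4 lower in rNLS8. The higher lists were interferon response (adjusted p = 2.6e-22), disease-associated microglia (5.9e-14), complement and antigen presentation (4.0e-09), lysosome and autophagy (8.6e-07), reactive astrocyte (1.6e-06), oligodendrocyte and myelin (0.00118), border macrophage and leukocyte (0.00129), homeostatic microglia (0.00422), integrated stress (0.0277) and cell cycle (0.0277). The lower lists were presynaptic vesicle (4.8e-06), upper cortical layers (0.00129), excitatory neuron (0.0102) and deep cortical layers (0.0212). With an estimated correlation no list passed, the smallest adjusted p being 0.389, and fry called deep cortical layers and cholesterol synthesis (both 0.00738). Adjusted over the list alone, 26 of 26 interferon genes, 19 of 30 genes of disease-associated microglia, 10 of 18 complement and antigen genes and 10 of 32 lysosomal genes passed as higher. Some lists share members, such as B2m and Ctsd, so these counts overlap. These tests do not adjust for the mix of regions. Fibre tracts took 2.67% of kept spots in control and 4.885% in rNLS8, and meninges and vessels 3.925% and 7.315%. Of the lists, only interferon response was followed with spots matched by region. Some list calls rested on 1 section. Homeostatic microglia lost its call without rNLS8 replicate 2 (adjusted p = 0.0882), excitatory neuron without control replicate 2 (0.0735) or rNLS8 replicate 1 (0.208), and upper layers without control replicate 2 (0.064). Deep layers lost it without control replicate 1 (0.067) or control replicate 2 (0.0667), integrated stress without control replicate 1 (0.351) or rNLS8 replicate 2 (0.0995), and cell cycle without control replicate 2 (0.192) or rNLS8 replicate 2 (0.451).

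In the cortex, 16 of 29 genes of disease-associated microglia, 11 of 26 interferon-response genes and 2 of 23 reactive astrocyte genes rose in rNLS8. Bst2 rose from 7.78 ± 1.51 CPM (SD, n = 2) in control to 83.5 ± 20.5 CPM in rNLS8, B2m from 58.6 ± 24.7 to 421 ± 60.2 CPM, and Gfap from 82.2 ± 9.99 to 644 ± 340 CPM. Ctsd, a lysosomal protease, rose from 104 ± 8.06 to 339 ± 68.2 CPM, and Cst7, a protease inhibitor of activated microglia, from 0.399 ± 0.151 to 32.8 ± 22.6 CPM. Nefl, the light subunit of neurofilaments, fell from 756 ± 51.8 to 294 ± 33.1 CPM, and Calb1, a calcium-binding protein of upper-layer neurons, from 386 ± 46.0 to 149 ± 19.2 CPM. The edgeR quasi-likelihood test called 152 of 12313 genes, 62 higher and 90 lower.

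Of 29 measured genes of disease-associated microglia, the state microglia take on around damaged tissue, 16 rose, 0 fell and 13 did not pass. Of these 29, 21 rose when adjusted over the list alone. Besides Cst7 (log2 fold change 6.28, SE 0.736, adjusted p = 0.0305), they held Cd52, a surface glycoprotein of immune cells (3.01, SE 0.293, adjusted p = 0.0272), Ctsd (1.70, SE 0.183, adjusted p = 0.0277) and Trem2, a lipid-sensing receptor of microglia (1.87, SE 0.281, adjusted p = 0.0423; 11.0 ± 2.61 to 40.5 ± 12.5 CPM). The others called were Fcer1g, B2m, Ctsz, Ctss, C1qa, C1qb, C1qc, Cd9, Tyrobp, Cd68, Lgals3bp and Tspo. Lgals3 (1.59, SE 0.440, adjusted p = 0.119) and Aif1, a general microglial marker (0.73, SE 0.311, adjusted p = 0.25), did not pass. The list's median log2 fold change was 1.59, and its camera adjusted p was 8.6e-17 (adjusted p = 0.423 with an estimated correlation).

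Of 19 homeostatic microglial genes, Fcrls alone passed, as higher (2.25, SE 0.346, adjusted p = 0.0435), and 7 rose when adjusted over the list alone. P2ry12 (0.43, SE 0.294, adjusted p = 0.447) and Csf1r (0.67, adjusted p = 0.117) did not pass. The list's median was 0.56 (camera adjusted p = 0.000194; adjusted p = 0.426 with an estimated correlation). Of 32 lysosome and autophagy genes, Ctsd, Ctss, Ctsz and Grn, the progranulin gene (1.36, SE 0.173, adjusted p = 0.0373), rose and 0 fell. Ctsd, Ctss and Ctsz are also counted among the genes of disease-associated microglia. Of the 32, 15 rose and 1 fell when adjusted over the list alone (median 0.44; camera adjusted p = 3.8e-07; adjusted p = 0.423 with an estimated correlation). The border macrophage and leukocyte list had 4 measured genes, of which the chemokine gene Ccl5 rose (1 UMI in control and 146 in rNLS8, a ratio of 127 with a 95% counting interval of 22.5 to 5059; adjusted p = 0.0277), and was not called (median 0.80; camera adjusted p = 0.11).

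Of 26 interferon-response genes, 11 rose, 0 fell and 15 did not pass, and all 26 rose when adjusted over the list alone. Cxcl10, a chemokine that draws T cells, rose from 0.292 to 33.5 ± 29.5 CPM (6.86, SE 1.09, adjusted p = 0.0455), Oasl2 from 5.03 to 54.1 CPM (3.42, SE 0.324, adjusted p = 0.0272), and Irf7, a transcription factor that amplifies interferon output, from 3.29 to 27.0 CPM (3.04, SE 0.433, adjusted p = 0.0399). Bst2 (3.42, SE 0.251, adjusted p = 0.0187), Usp18 (2.90, SE 0.337, adjusted p = 0.0295), Irf9 (2.06, SE 0.202, adjusted p = 0.0272), Ifit1, Ifi27, Rtp4 and Psmb8 also rose. So did Ifi27l2a, whose value is uncertain because Ifi27l2b is a near-identical copy. The list's median was 2.27 (camera adjusted p = 1.0e-20; adjusted p = 0.423 with an estimated correlation). Of 15 complement and antigen presentation genes, 6 rose and 0 fell: B2m (2.84, SE 0.294, adjusted p = 0.0277), C1qa (1.54, SE 0.228, adjusted p = 0.0423), C1qb, C1qc, C3ar1 and C4b, which C4a resembles closely enough that the value is uncertain between them (2.82, SE 0.308, adjusted p = 0.0277; 14.6 ± 2.44 to 103 ± 41.1 CPM). Of the 15, 11 rose when adjusted over the list alone (median 1.68, camera adjusted p = 1.3e-09, and adjusted p = 0.423 with an estimated correlation). B2m, C1qa, C1qb and C1qc are also among the called genes of disease-associated microglia, so these calls are not separate.

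Of 23 reactive astrocyte genes, Gfap (2.97, SE 0.365, adjusted p = 0.0329) and C4b, also counted among the complement genes above, rose and 0 fell. Adjusted over the list alone, 5 rose. Vim (1.05, adjusted p = 0.087) and S100a6 (1.18, adjusted p = 0.0595) did not pass. The list's median was 0.58 (camera adjusted p = 3.4e-05; adjusted p = 0.426 with an estimated correlation). General astrocyte markers did not shift as a list (median 0.00, camera adjusted p = 0.969), and Aqp4, the astrocyte water channel, stood at 0.94 (adjusted p = 0.0917). Oligodendrocyte and myelin genes were called as a list with 0 genes passing (median 0.17; camera adjusted p = 0.0195; adjusted p = 0.426 with an estimated correlation), a call lost without control replicate 2 (adjusted p = 0.258) and without rNLS8 replicate 1 (0.142). Oligodendrocyte precursor genes (median 0.04 against a camera direction of lower, adjusted p = 0.895), endothelial and mural genes (-0.10, adjusted p = 0.743) and meningeal and choroid plexus genes (median 0.12 against a mean of -0.00095, adjusted p = 0.834) were not called.

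Of 24 presynaptic vesicle genes, Stx1a, a membrane fusion protein (-0.97, SE 0.141, adjusted p = 0.0411; 194 to 98.8 CPM), and Unc13a, which primes vesicles for release (-0.87, SE 0.134, adjusted p = 0.0435; 226 to 124 CPM), fell and 0 rose. The other 22 did not pass, among them Snap25 (-0.87, adjusted p = 0.0583) and Vamp2 (-0.71, adjusted p = 0.0602). As many as 14 fell when adjusted over the list alone (median -0.46; camera adjusted p = 5.0e-09; adjusted p = 0.423 with an estimated correlation). Of 10 upper-layer genes, Calb1 (-1.37, SE 0.166, adjusted p = 0.0329), Lamp5 (-1.92, SE 0.273, adjusted p = 0.0399; 228 to 60.2 CPM) and Rasgrf2 (-0.96, SE 0.145, adjusted p = 0.0423) fell and 0 rose. Adjusted over the list alone, 5 fell (median -0.62; camera adjusted p = 2.9e-05; adjusted p = 0.423 with an estimated correlation). Of 17 deep-layer genes, Rprm fell (-1.35, SE 0.156, adjusted p = 0.0295; 106 to 41.6 CPM), and 0 rose. Adjusted over the list alone, 5 fell (median -0.23; camera adjusted p = 0.0121; adjusted p = 0.423 with an estimated correlation; 0.102 by camera without control replicate 2). None of 16 excitatory neuron genes passed, including Nrgn (-1.09, adjusted p = 0.0515) and Cck (-0.94, adjusted p = 0.0595). Of the 16, 7 fell when adjusted over the list alone (median -0.42; camera adjusted p = 6.6e-05; adjusted p = 0.423 with an estimated correlation). Of 18 axon and cytoskeleton genes Nefl fell (-1.36, SE 0.153, adjusted p = 0.0288) and 0 rose. Of the 18, 4 fell and 1 rose when adjusted over the list alone (median -0.24; camera adjusted p = 0.0121; adjusted p = 0.423 with an estimated correlation; 0.0755 by camera without rNLS8 replicate 2).

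Lists tied to excitability were not called as lists, although single members passed. Among activity-regulated genes Nptx2, a secreted protein that gathers glutamate receptors, fell (-1.73, SE 0.172, adjusted p = 0.0272; 37.5 to 11.3 CPM) and Btg2 rose (1.49, SE 0.225, adjusted p = 0.0423). Adjusted over the list alone, 5 rose and 6 fell, and the list's median was -0.14 (camera adjusted p = 0.219). The potassium channel gene Kcnv1 fell (-1.04, SE 0.175, adjusted p = 0.0483; list median -0.05, camera adjusted p = 0.0936), and so did Gria3, an AMPA-type glutamate receptor subunit (-1.27, SE 0.199, adjusted p = 0.0435; list median -0.02, camera adjusted p = 0.12). No sodium, calcium or HCN channel gene passed (Scn4b -1.25, adjusted p = 0.149; list median -0.12, camera adjusted p = 0.27), nor any GABA receptor gene (list median -0.21, camera adjusted p = 0.0936). Among inhibitory neuron genes the neuropeptide gene Npy fell (-0.99, SE 0.160, adjusted p = 0.0455) and Cort, whose 2 control sections held 0 UMI, was at least 10.8-fold higher against a floor of 3 counts per section (list median -0.21, mean 0.21, camera adjusted p = 0.292). Variants under its probes are a candidate explanation for the 0 counts of Cort, so its value is not read as a rise.

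Among injury and stress genes, Atf3, a transcription factor of injured neurons, rose from 0.544 to 9.49 ± 5.16 CPM (4.09, SE 0.580, adjusted p = 0.0399). Tnfrsf12a, a receptor tied to nerve regrowth, rose as well (2.68, SE 0.353, adjusted p = 0.0376), while the neuronal injury list as such was not called (median 0.00, camera adjusted p = 0.589). Atf3 was also the called gene of 28 integrated stress and unfolded protein genes, of which 7 rose and 1 fell when adjusted over the list alone (median 0.43; camera adjusted p = 0.00564; adjusted p = 0.521 with an estimated correlation). Of 18 cholesterol synthesis genes, Sqle, which makes squalene epoxide, fell (-0.99, SE 0.153, adjusted p = 0.0435; list median -0.22; camera adjusted p = 0.0116; adjusted p = 0.423 with an estimated correlation). Among genes linked to amyotrophic lateral sclerosis, Grn rose and Unc13a fell (list median -0.06, mean 0.32, camera adjusted p = 0.615). Tardbp was also called as higher, but with 0 UMI in both control sections this cannot be read as a rise of the mouse gene. Heat shock (median 0.02, camera adjusted p = 0.681), oxidative phosphorylation (-0.07, camera adjusted p = 0.15), proteasome (0.09, camera adjusted p = 0.589) and cell cycle lists (0.46, camera adjusted p = 0.0978; Mki67 2.1, adjusted p = 0.0867) were not called.

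The largest falls outside these lists were in Agmat, which encodes agmatinase (-3.26, SE 0.534, adjusted p = 0.0459), Irgc1 (-3.16, SE 0.442, adjusted p = 0.0399), Igfn1 (-2.92, SE 0.188, adjusted p = 0.0152; 60.1 ± 0.207 to 7.91 ± 1.34 CPM), Qrfpr, a neuropeptide receptor (-2.68, SE 0.399, adjusted p = 0.0423), and Lrg1 (-2.64, SE 0.376, adjusted p = 0.0399). Fst, an activin antagonist (-2.38, SE 0.362, adjusted p = 0.0427), Cbln4, a synaptic organizer (-2.30, SE 0.341, adjusted p = 0.0423; 57.4 to 11.5 CPM), Plk5 (-2.14, SE 0.263, adjusted p = 0.0329), Muc3a (-2.08, SE 0.226, adjusted p = 0.0277) and Tnnc1, a troponin (-2.02, SE 0.340, adjusted p = 0.0492), completed the 10 largest. Among the 10 largest rises, Tent5c, a poly(A) polymerase, belongs to no list (3.09, SE 0.518, adjusted p = 0.0483).

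**Figure D2:**
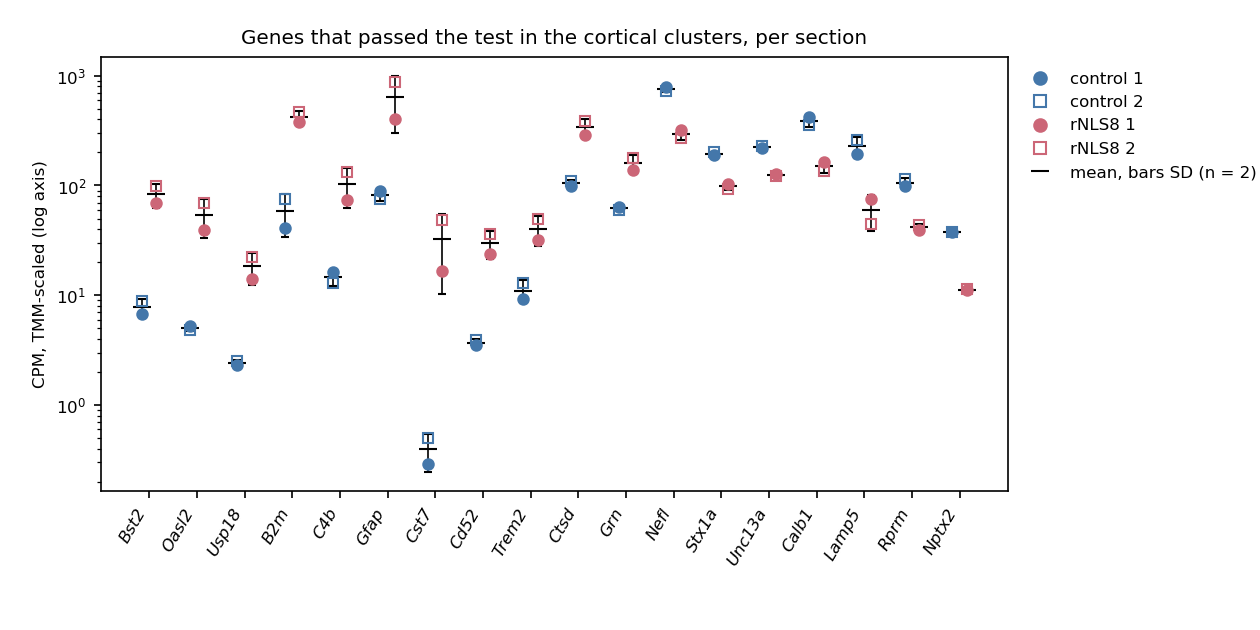
Cortical levels of 18 genes in CPM on a log axis, with 1 point per section and the mean and SD of the 2 sections of each group. Bst2 lies at 7.78 CPM on average in control and 83.5 CPM in rNLS8, and Nefl at 756 and 294 CPM.

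The 152 calls depended on the sections and on how the cortex was drawn. With 1 control section left out, spread came from the rNLS8 pair alone. Over whole sections that pair differed less than the control pair (chi-square per degree of freedom 18.5 against 46.3). Such a fit cannot test how the control sections bear on the 152 calls. Of them, 59 were among the 88 called without rNLS8 replicate 1 and 19 among the 20 called without rNLS8 replicate 2. The balance of 62 higher and 90 lower turned in these 2 fits (63 and 25, and 14 and 6). DESeq2 called 691, with 151 of the 152. Of the genes named, Tardbp, Cxcl10, Ccl5, Cst7, Oasl2, Bst2, Igfn1, Cbln4, Plk5, Cd52, B2m, Irf9, C4b, Gfap and Tnfrsf12a were called without each section in turn. The log2 fold change of Gfap was 2.29 and that of Cst7 5.32 without rNLS8 replicate 2, and that of Cbln4 was -3.02 without rNLS8 replicate 1. That of Cxcl10 was 5.45 without rNLS8 replicate 2, and the cortex of control replicate 2 held 0 UMI of it. Tent5c gave 2.49 without control replicate 1 and 4.22 without control replicate 2. Without rNLS8 replicate 2, Irf7 gave 2.38, Atf3 3.39 and Irgc1 -3.84. The other called genes given with an SE lost their call without rNLS8 replicate 1, without rNLS8 replicate 2, or in both cases. In the cortex 6803 genes (55.3%) did not overlap between groups, where chance gives 33.3%.

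The cortex was the union of clusters 3, 6, 7, 8 and 13, and the groups filled these unevenly. Cluster 6 held 22 and 78 spots in the control sections and 372 and 387 in the rNLS8 sections. Its 10 leading genes included Cst7, Cxcl10, B2m and Cd52 but no cortical marker. Over whole marker lists it led for cortex of all layers (mean log2 lead 0.52), ahead of midbrain and brainstem (0.1). Cluster 8 held 419 and 286 spots in control and 14 and 2 in rNLS8. Of 1002 and 766 cortical spots in control and 859 and 959 in rNLS8, the upper-layer cluster 7 held 220 and 194 against 149 and 162, and the deep-layer cluster 13 held 105 and 61 against 42 and 29, which bears on the falls of layer genes. The rule set beforehand counts as cortical only clusters whose leading genes hold cortical layer markers. Keeping cluster 6 departed from it, so the 152 calls do not follow that rule. Leaving cluster 6 out selects on the outcome as well, since its leading genes are among those compared. Fits run after seeing the data left cluster 6 out, as the rule asks (47 genes called, 45 of them among the 152). Others took cluster 3 alone (63, with 41 shared) or cluster 7 alone (259, with 104 shared). Gfap, C4b, B2m, Bst2, Oasl2, Ctsd, Calb1, Nptx2 and Nefl were called under each of these 3, Gfap with log2 fold changes of 2.27, 2.06 and 1.90, and Bst2 with 2.87, 2.49 and 2.85. Trem2 was called under none of them (1.16, 1.24 and 1.15), and C1qa under none (0.93, 0.91 and 0.80). Without cluster 6, the genes that lost their call included Cxcl10, Ccl5, Atf3, Irf7, Tent5c, Fcrls, Lamp5, Stx1a, Unc13a, Grn, C1qc and Agmat, and the myelin and deep-layer lists lost theirs (camera adjusted p = 0.648 and 0.102). Cluster 3 alone kept no call for homeostatic microglia, deep layers, axon and cytoskeleton, and cholesterol synthesis, and cluster 7 alone none for these 4 lists, reactive astrocyte, myelin and integrated stress.

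**Figure D3:**
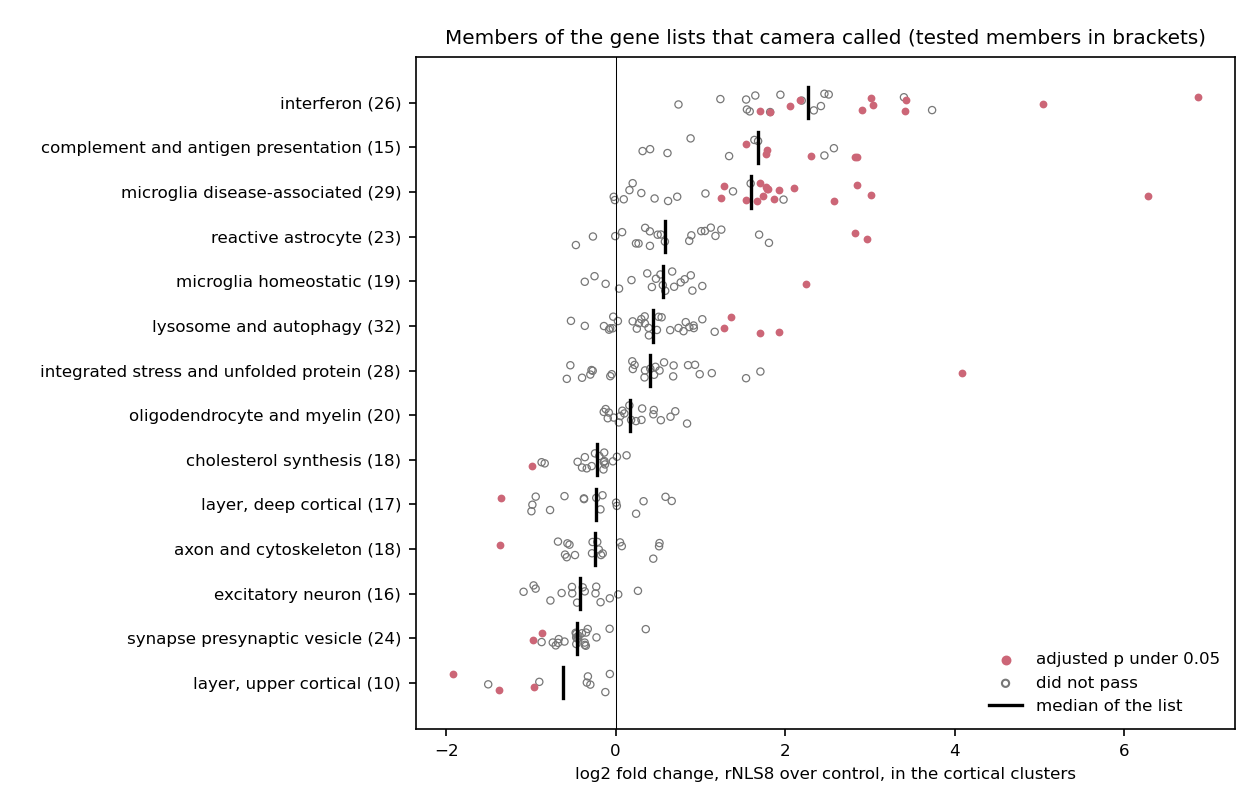
Log2 fold changes of the measured members of the 14 lists called in the cortex, with 1 point per gene, red where the adjusted p is under 0.05, and a line at the list's median. The median is 2.27 for interferon response, 1.59 for disease-associated microglia and -0.62 for upper cortical layers.

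Interferon-response genes also rose outside the cortex. In the striatum, a deep nucleus of inhibitory projection neurons, Cxcl10 rose from 0.544 to 21.6 CPM (5.28, SE 0.377, adjusted p = 0.00685) and Bst2 from 9.21 to 61.9 CPM (2.73, SE 0.218, adjusted p = 0.00811). B2m rose from 39.5 to 254 CPM (2.67, SE 0.241, adjusted p = 0.0141) and Gfap from 119 to 374 CPM (1.65, SE 0.241, adjusted p = 0.0366). Prkcb fell from 1029 to 361 CPM (-1.51, SE 0.161, adjusted p = 0.0188), and Camkk2 from 422 to 147 CPM (-1.52, SE 0.167, adjusted p = 0.0188). Dgkb, a diacylglycerol kinase, fell from 1012 to 423 CPM (-1.26, SE 0.150, adjusted p = 0.0209) and Nefl from 474 to 244 CPM (-0.96, SE 0.144, adjusted p = 0.0393). Of 12079 genes 65 were called, 29 higher and 36 lower. The groups filled the 2 striatal clusters unevenly: cluster 1 held 334 and 237 spots in control and 681 and 340 in rNLS8, and cluster 5 held 398 and 414 in control and 49 and 34 in rNLS8. Of 24 interferon genes 9 rose, with a list median of 1.72, and 5 of 29 genes of disease-associated microglia rose, with a median of 0.75. The striatal list tests were added after seeing the data and gave camera adjusted p = 2.9e-22 for interferon response and 2.2e-13 for disease-associated microglia (adjusted p = 0.246 and 0.495 with an estimated correlation, and 0.00556 and 0.122 by fry). Of the 13 lists called, complement and antigen presentation (5.3e-10), reactive astrocyte, lysosome and autophagy (3.7e-05), border macrophage (0.0396), homeostatic microglia (0.0447) and meninges and choroid plexus genes (0.0478) were also higher. Presynaptic vesicle (0.00106), upper-layer (0.00153), deep-layer (0.0287), excitatory neuron (0.0319) and glutamate receptor genes (0.0396) were lower. None of the 13 passed with an estimated correlation (adjusted p = 0.246 or above with an estimated correlation), and fry called interferon response, lysosome and autophagy (0.0373) and border macrophage genes (0.0242). The count of called genes was 837 without control replicate 1, 2142 without control replicate 2 and 12 without rNLS8 replicate 2, of which 9 were among the 65. Without rNLS8 replicate 1 it was 65, of which 30 were the same genes.

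In fibre tracts 41 of 8752 genes were called, 26 higher and 15 lower (15 and 18 with DESeq2). B2m rose from 67.3 to 466 CPM (2.79, SE 0.306, adjusted p = 0.0015), C4b from 135 to 389 CPM (1.52, SE 0.199, adjusted p = 0.00515) and Gfap from 803 to 1836 CPM (1.19, SE 0.231, adjusted p = 0.0368), while Myl4, a myosin light chain, fell from 104 to 34.5 CPM (-1.61, SE 0.278, adjusted p = 0.0181). The edgeR count was 0 without control replicate 1, 763 without control replicate 2, 80 without rNLS8 replicate 1 and 9 without rNLS8 replicate 2. In meninges and vessels 21 of 9730 genes were called, 9 higher and 12 lower (7 and 42 with DESeq2). Cd52 rose from 2 UMI in control to 76 in rNLS8 (a ratio of 18.4 with a 95% counting interval of 4.92 to 155; adjusted p = 0.0376) and B2m from 163 to 602 CPM (1.89, SE 0.197, adjusted p = 0.00473), and Igfn1 fell (-3.29, SE 0.417, adjusted p = 0.00923). That count was 226 without control replicate 1, 1036 without control replicate 2, 36 without rNLS8 replicate 1 and 8 without rNLS8 replicate 2. The groups did not overlap in 48.9% of striatal, 44.7% of fibre tract and 42.7% of meningeal genes, where chance gives 33.3%. The genes named for these 3 regions were chosen after their values were seen, and the regions come from the same sections as the cortex.

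The rise of Gfap was larger in cortical spots (log2 fold change 2.93) than in all other spots (1.57), a difference of 1.38 (SE 0.0909, adjusted p = 3.7e-05). So was that of C4b (2.75 and 1.58; difference 1.17, SE 0.132, adjusted p = 0.00763) and of the phagocyte gene Cd68 (1.74 and 0.82; difference 0.94, SE 0.160, adjusted p = 0.0482). Cbln4 was lower by more in cortical spots (-2.29 and -0.89; difference -1.47, SE 0.207, adjusted p = 0.0237), and Cyp26b1, which breaks down retinoic acid, had a difference of -2.50 (SE 0.382, adjusted p = 0.0305). Its cortical levels overlapped between groups (25.2 and 8.71 CPM in control, 6.54 and 9.93 in rNLS8) and did not pass in the cortex alone (adjusted p = 0.299), and the difference was -1.81 without control replicate 1. Smoc2 (difference -0.99, SE 0.172, adjusted p = 0.0484), Cited4 (-0.90, SE 0.135, adjusted p = 0.0305) and Parva (-0.73, SE 0.126, adjusted p = 0.0484) had differences below 0, and Mafa (1.37, SE 0.238, adjusted p = 0.0484) and Arhgdib (1.13, SE 0.139, adjusted p = 0.0127) above 0. The interaction test of edgeR called 23 of 12969 genes, 13 with a larger and 10 with a smaller log2 fold change in the cortex. Trem2 (0.93, adjusted p = 0.0865), Lgals3 (1.31, adjusted p = 0.2), P2ry12 (0.35, adjusted p = 0.524) and Aif1 (0.32, adjusted p = 0.477) did not pass. The count was 1 without either control section, 672 without rNLS8 replicate 1 and 141 without rNLS8 replicate 2. Gfap was called without each section in turn, and the other 9 genes named here were not called without control replicate 1 or without control replicate 2 (adjusted p from 0.0616 to 0.669). The cortical side includes cluster 6, which departs from the rule set beforehand for cortical clusters. In a fit without cluster 6, added after seeing the data, 50 genes were called, 13 of them among the 23. The difference for Gfap was then 0.75 (adjusted p = 0.0389), while C4b (0.68, adjusted p = 0.126), Cd68 (0.36, adjusted p = 0.618) and Smoc2 (-0.59, adjusted p = 0.298) were not called. As cluster 6 is led by immune genes compared here and lies mainly in rNLS8, its removal can by itself lower such differences.

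Lists were compared between the cortex and the other spots in a test added after seeing the data. Disease-associated microglia (median difference 0.50; camera adjusted p = 6.4e-16), complement and antigen presentation (0.57; 5.6e-06), interferon response (0.37; 0.000103), lysosome and autophagy (0.07; 0.000103), homeostatic microglia (0.22; 0.00017) and integrated stress (0.13; 0.00145) had higher log2 fold changes in the cortex. Presynaptic vesicle (-0.21; 1.0e-08), endothelial and mural (-0.24; 0.00101) and excitatory neuron genes (-0.24; 0.00269) had lower ones, as had meninges and choroid plexus (-0.51; 0.00539), upper cortical layers (-0.28; 0.00539), cholesterol synthesis (-0.16; 0.00539), oligodendrocyte and myelin (-0.11; 0.00796) and axon and cytoskeleton genes (-0.15; 0.0129). Reactive astrocyte genes as a list did not differ by this test (camera adjusted p = 0.26). With an estimated correlation the smallest adjusted p was 0.284. Without cluster 6, none of the 6 lists above 0 was called: disease-associated microglia had a median difference of 0.03 (camera adjusted p = 0.682), complement and antigen presentation 0.05 (0.957) and interferon response -0.13 (0.595). Cluster 6 is led by members of these lists, such as Cst7, Cxcl10, B2m and Cd52. It held 22 and 78 spots in control and 372 and 387 in rNLS8. Leaving it out removes spots rich in these genes mainly from rNLS8, while cluster 8, filled mainly by control, stayed in. The loss therefore does not show that the cortical excess is absent. Of the lists below 0, presynaptic vesicle, endothelial and mural, meninges and choroid plexus, and myelin genes kept their call. The others lost it with median differences still below 0: excitatory neuron -0.19, upper layers -0.23, cholesterol synthesis -0.10, and axon and cytoskeleton -0.10.

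Within the cortex, 22 of 9724 genes responded differently in the upper-layer cluster and in the deep-layer cluster, 1 with a larger and 21 with a smaller log2 fold change in the upper layers. The log2 fold change of Kcnab2, an auxiliary subunit of potassium channels, was 1.04 in the upper and 0.35 in the deep layers (difference 0.66, SE 0.120, adjusted p = 0.00493). Clic5 (difference -2.04, SE 0.450, adjusted p = 0.0281), Spata13 (-2.0, SE 0.449, adjusted p = 0.0301), and Rilpl1 (-1.52, SE 0.313, adjusted p = 0.0144) had smaller log2 fold changes in the upper layers. Of the 22, Bhlhe22 and Cplx3 are the first leading genes of the upper-layer and the deep-layer cluster, so the spots were selected on them and their differences are not read. Gfap (-0.60, adjusted p = 0.128), Trem2 (-0.42, adjusted p = 0.907), P2ry12 (-0.36, adjusted p = 0.918) and Aif1 (0.10, adjusted p = 0.98) did not pass. The edgeR test had 816 genes at an unadjusted p under 0.05, DESeq2 called 0, and edgeR called 0 without control replicate 1, 1 without control replicate 2 and 2 without rNLS8 replicate 2. When the clustering did not centre genes within sections, the difference was -0.19 for Clic5 and -1.66 for Gfap. The deep-layer cluster held 105 and 61 spots in control and 42 and 29 in rNLS8. Its markers led for deep layers (mean log2 lead 0.79) but nearly as much for fibre tracts (0.69), so it need not stand for the deep layers as a whole. With deep layers as all other cortical clusters, 65 genes were called, and only 10 of the 22 were among them.

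Spatial patterning was compared through Moran's I, a score of how strongly a gene's level in a spot follows that of its neighbours. The score was not adjusted for a gene's level or for the mix of regions. B2m had a higher score in rNLS8, with Moran's I of 0.0132 and 0.0441 in the control sections and 0.240 and 0.217 in the rNLS8 sections (difference 0.20, SE 0.0162, adjusted p = 0.00563). Its level was also higher in rNLS8, so a change of pattern cannot be told apart from one of level. Six3, a homeobox transcription factor, went from 0.172 and 0.166 to 0.316 and 0.366 (difference 0.172, SE 0.0165, adjusted p = 0.0106). limma called these 2 of 6321 genes as higher and 0 as lower, with 907 at an unadjusted p under 0.05. The typical score of a gene was 0.0341 and 0.0331 in the control sections and 0.0251 and 0.0158 in the rNLS8 sections. It was thus lower in rNLS8, so the 2 calls do not stand for a general rise, and lower scores of single genes need not be particular to them. Gfap (0.162, adjusted p = 0.144), Camkk2 (-0.130, adjusted p = 0.0704) and Tafa1 (-0.0673, adjusted p = 0.0693) did not pass. With the replicate number as a replicate block, which pairs no animals, limma called neither B2m nor Six3, and over genes in 1% of spots it called B2m (adjusted p = 0.0212) but not Six3 (0.0505). Neither gene was among those in 50% of spots, so that setting does not test them. Leaving out control replicate 1, control replicate 2, rNLS8 replicate 1 or rNLS8 replicate 2 gave 7, 5, 60 or 43 calls, with both genes among them each time.

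In the rNLS8 cortex, spots rich in transcripts of the disease-associated microglia list had neighbours rich in transcripts of the reactive astrocyte list. The Spearman correlation between the share of UMI from the microglial list in a spot and the share from the astrocyte list in its neighbours was 0.0458 and 0.0197 in the control sections and 0.374 and 0.569 in the rNLS8 sections. With the neighbours' share of neuronal genes it was -0.0445 and -0.0809 in control and -0.205 and -0.320 in rNLS8 (without thinning -0.0455 and -0.0684 against -0.251 and -0.428), and with the same microglial list in the neighbours 0.0697 and 0.155 against 0.406 and 0.565. The microglial list took 0.305% and 0.344% of cortical UMI in control and 0.527% and 0.639% in rNLS8, and the astrocyte list 0.0340% and 0.0330% against 0.0846% and 0.154%. Lower shares give noisier correlations. A share sums all genes of a list, so it does not show which cell type held the transcripts. Spots were thinned to 3000 UMI, include cluster 6, are not replicates, and carry no p.

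**Figure D4:**
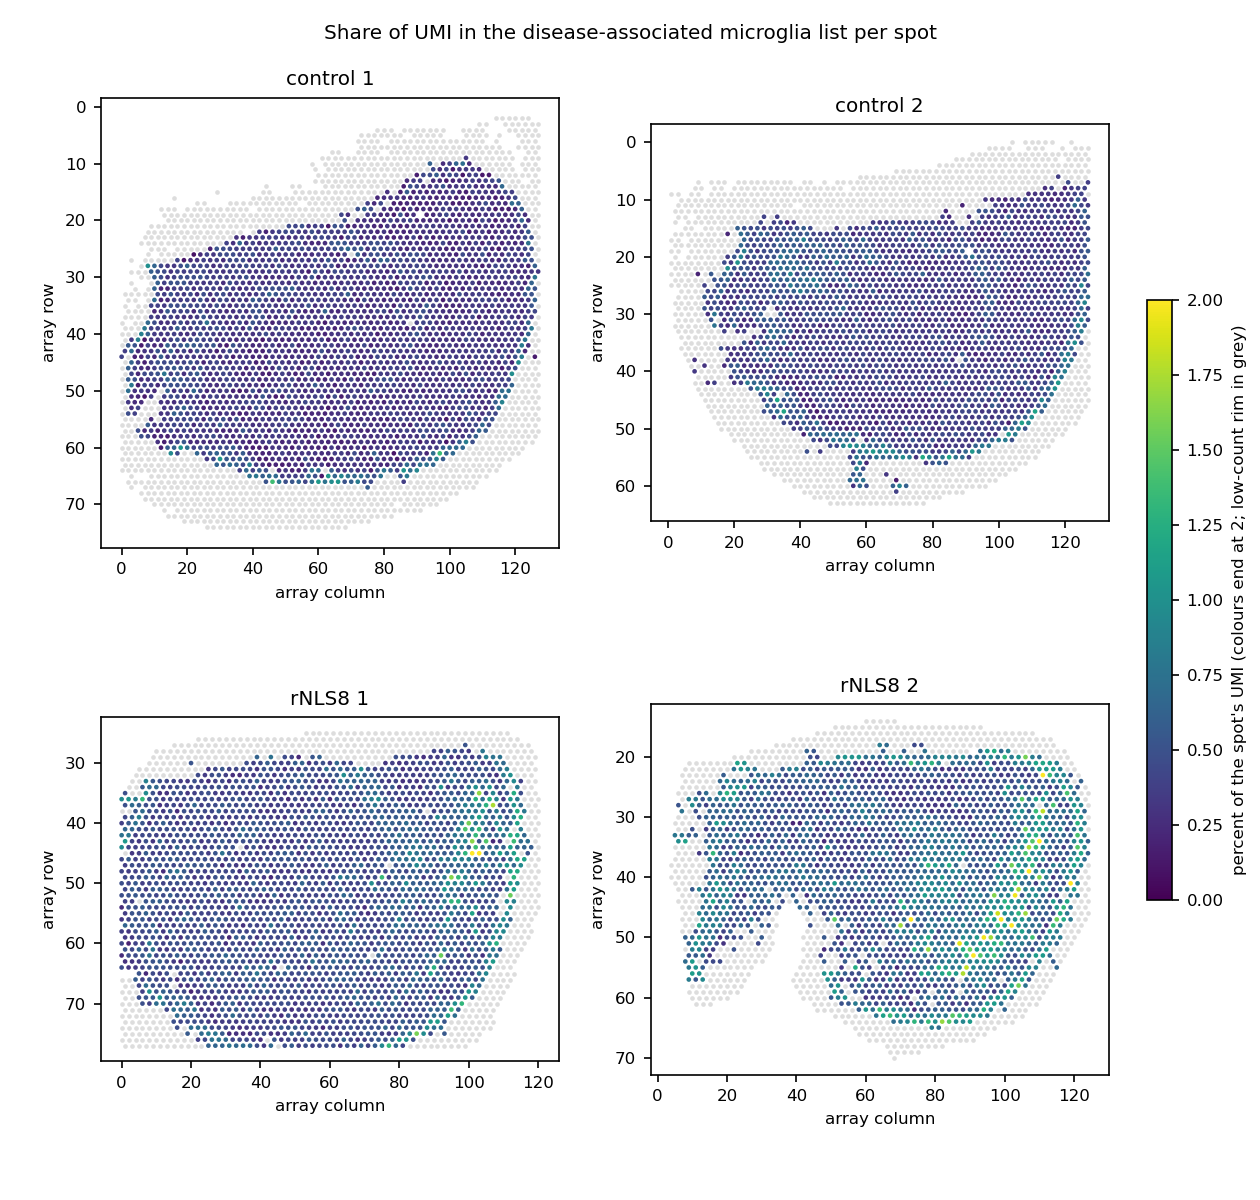
Percent of UMI from the list of disease-associated microglia in each spot of the 4 sections, by array column and row, with the colour scale ending at 2 and the low-count rim in grey. In cortical spots thinned to 3000 UMI, the list took 0.305% and 0.344% in control and 0.527% and 0.639% in rNLS8.

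The sections did not sample the same mix of regions. Cortex took 24.7% ± 2.21 (SD, n = 2) of kept spots in control and 32.2% ± 5.50 in rNLS8, fibre tracts 2.67% ± 0.566 and 4.88% ± 0.757, meninges and vessels 3.92% ± 0.955 and 7.32% ± 2.98, and a low-count rim at the section edge 33.4% ± 2.62 and 21.1% ± 5.71. The cortical share was 26.3% (95% exact binomial interval 24.9% to 27.7%) in control replicate 1, 23.2% (21.7% to 24.6%) in control replicate 2, 28.3% (26.7% to 30%) in rNLS8 replicate 1 and 36.1% (34.3% to 38.0%) in rNLS8 replicate 2. Striatum took 19.4% ± 0.339 in control and 19.1% ± 7.06 in rNLS8. The exact two-sided permutation test gave p = 0.333 for cortex, fibre tracts, meninges and rim, the smallest value that 2 against 2 sections allow, and p = 1 for striatum.

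Tardbp, the mouse gene for TDP-43, was read at 0 UMI in both control sections and at 197 and 138 UMI in the rNLS8 sections. A count of 0 allows up to 0.158 CPM in control replicate 1 and 0.126 CPM in control replicate 2, while the rNLS8 sections stood at 7.02 and 7.83 CPM before scaling. The gene was at least 17.6-fold higher in the rNLS8 cortex (adjusted p = 0.0277) and at least 16.7-fold higher in the rNLS8 striatum (adjusted p = 0.0209), against a floor of 3 counts per section. Whether the probes read the mouse gene, the human transgene or both is not given in the sources used here. The 4 Y-linked genes measured summed to 0 CPM in control replicate 1, labelled female, 107 CPM in control replicate 2, labelled male, 137 CPM in rNLS8 replicate 1, labelled female, and 139 CPM in rNLS8 replicate 2, labelled male.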

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

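Of the tests below, the interaction tests and that of matched spots were set before their results were seen, and those of RNA spread between regions in the form given, depth, probe set, linked genes, transgene, spill-over, exchanged or mislabelled sections and sex, and the fit without cluster 6, were chosen only after the result was seen.

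Tardbp and Cort had 0 UMI in both control sections, where their rNLS8 levels predict 461.5 UMI of the pair, which argues against lower depth as the cause. A different probe set in the control sections is argued against by the small number of genes with 0 UMI in both control sections and a mean of at least 2 CPM in rNLS8, which is 3 (Tardbp, Cort and Pigv). Tardbp and Cort lie 0.506 Mb apart on chromosome 4 (148612382 to 148627084 and 149125034 to 149126763), and 0.3145% of random sets of 3 genes hold a pair as close, so variants under the probes of linked genes, left from another mouse strain, are a candidate explanation. A product of the human transgene read by the Tardbp probes stays open, since the ratio of Tardbp in cortical over other spots averaged 1.034 (1.26, 95% interval 0.933 to 1.69, and 0.808, 0.566 to 1.15), and a transgene active in neurons of many regions sets no bound on it. The rise of Tardbp in rNLS8 therefore cannot be read as a rise of the mouse gene.

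Interferon-response genes had higher values in the cortex and in the striatum. In the cortex 11 of 26 were called, and in the striatum also only a part. With an estimated correlation, camera called the list in neither. The rise inside single regions argues against different shares of the named regions as the cause. Matched spots add little to that: with 2070 spots of each section matched by region, the median log2 fold change of the 26 genes was 1.942. Clusters inside regions were not matched, and the groups filled the cortical and striatal ones unevenly. A different makeup inside regions therefore stays open. Spread of RNA from cortical spots stays open: the median striatal excess of these genes was 0.884 of the cortical excess in rNLS8 replicate 1 (22 genes, 95% bootstrap interval 0.792 to 1.04) and 0.5035 in rNLS8 replicate 2 (25 genes, 0.374 to 0.587), above the median of 9 cortical markers (0.352 and 0.356) but not above their highest (1.04 and 0.931). In a first version of that test with 6 markers, both medians exceeded the highest marker (0.484 and 0.458), in rNLS8 replicate 2 by less than the interval. The marker set and the interval were changed after that was seen. The markers added were Stx1a, Nrn1 and Lamp5, and a marker made in the striatum itself would raise the bar. The outcome rests on the choice of markers, so the test cannot decide. The labels name no slide or batch, so none was tested, and the response of the tissue to the transgene stays among the open explanations.

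As a check of the labels, Y-linked genes were summed, which gave 136.7 CPM in the library labelled rNLS8 replicate 1 and female, against 0 in control replicate 1, labelled female. Spill-over from a male section is argued against, since the level was 1.11 times the mean of the sections labelled male. An exchange with a control section is argued against by the 197 UMI of Tardbp in that library, where both control sections had 0, and an exchange with the other rNLS8 section by the 139.1 CPM of Y-linked genes there. A wrong sex label or an animal from outside the series is consistent with the same ratio of 1.11. Control replicate 1 is then the only section without Y-linked transcripts. With it left out, the median log2 fold change of the interferon list was 1.927 in the cortex (95% bootstrap interval over genes 1.73 to 2.88) and 1.624 in the striatum (1.40 to 2.49). These intervals do not cover spread between sections, and a single control section remained. For these sections the medians argue against sex as the whole cause of that rise, and leave it open for other differences.

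The effect of genotype differed between the cortex and all other spots in 23 genes by the interaction test. The difference of log2 fold change was 1.384 for Gfap, 1.369 for Mafa, 1.174 for C4b, 1.128 for Arhgdib and 0.9429 for Cd68. It was -2.503 for Cyp26b1, -1.471 for Cbln4, -0.9941 for Smoc2, -0.895 for Cited4 and -0.733 for Parva. With cluster 6, which the rNLS8 sections fill more, left out of the cortex, it was 0.7463 for Gfap, and C4b, Cd68 and Smoc2 were not called. Cluster 6 is led by immune genes of the lists, so leaving it out selects on the outcome.

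The effect differed between the upper-layer and the deep-layer cluster in 22 genes by the interaction test. The difference was 0.6637 for Kcnab2, -2.044 for Clic5, -2.002 for Spata13 and -1.524 for Rilpl1. Cplx3 and Bhlhe22, also called, lead the deep-layer and the upper-layer cluster, so their spots were selected on them.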

How the results depend on the processing

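The replicate block with crossed numbers, the cortex without cluster 6 or as cluster 3 or 7 alone, deep layers as all other cortical clusters, and the fits without the rim or the spots next to meninges were chosen after seeing the data; the other alternatives were planned. Counts of called genes follow, and their cause was not tested except where fewer genes, spots or sections were used. Where 1 section was left out, the lone section of its group was assumed to vary like the others, and depth limited the thinned sums and the filter at 50 counts.

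For whole sections, 0 calls became 529 with DESeq2, 239 with no filter on low counts, 7 with region-matched spots, and 2 to 1839 when 1 section was left out. They stayed at 0 with DESeq2 size factors, at least 50 counts, all spots, thinned sums or no rim, where edgeR had 2093 genes at an unadjusted p under 0.05 in the reported fit. For the cortex, 152 calls became 691 with DESeq2, 702 with no filter, 42 with at least 50 counts, 55 with thinned sums, 67 without centring, 47 without cluster 6, 63 in cluster 3 alone, 259 in cluster 7 alone, and 20 to 4418 when 1 section was left out. More were higher than lower without rNLS8 replicate 1 (63 and 25), without rNLS8 replicate 2 (14 and 6) and with thinned sums (28 and 27), against 62 and 90 as reported. The count stayed within 1.5 times (123 to 201) with DESeq2 size factors, all spots, both Leiden resolutions and without spots next to meninges.

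The striatal 65 became 350 with DESeq2, 788 with no filter, 160 with thinned sums and 12 to 2142 with 1 section left out; without rNLS8 replicate 2, 10 were higher and 2 lower, against 29 and 36. The 41 in fibre tracts became 207 with no filter, 17 with at least 50 counts, 20 with thinned sums, 12 and 21 at Leiden resolutions 0.5 and 2.0, 18 without centring (9 higher and 9 lower) and 0 to 763 with 1 section left out. Against 26 higher and 15 lower, DESeq2 gave 15 and 18, at least 50 counts 8 and 9, resolution 0.5 4 and 8, and the fit without control replicate 2 338 and 425. The 21 in meninges and vessels (9 higher and 12 lower) became 49 with DESeq2 (7 and 42), 194 with no filter, 11 with all spots and 8 to 1036 with 1 section left out. Without centring 19 were called, 6 higher and 13 lower, and more were higher than lower without rNLS8 replicate 1 (21 and 15) or 2 (7 and 1).

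The 23 differences between cortex and other spots became 11 with DESeq2 size factors, 171 with no filter, 11 with at least 50 counts, 61 at Leiden resolution 0.5, 50 without cluster 6 (21 higher and 29 lower, 13 of them among the 23) and 1 to 672 with 1 section left out; without centring 30 were called, 13 higher and 17 lower. Against 13 higher and 10 lower, no filter gave 70 and 101, resolution 0.5 25 and 36, and the fits without rNLS8 replicate 1 and 2 gave 233 and 439, and 53 and 88. The 22 differences between layers became 0 with DESeq2, 45 with no filter, 39 with at least 50 counts, 48 with all spots, 11 with thinned sums, 91 at Leiden resolution 0.5, 99 without centring (23 higher and 76 lower), 65 with deep layers as all other cortical clusters, and 0 to 25 with 1 section left out.

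The 14 lists of whole sections became 0 with an estimated correlation, 2 with fry (both lower) and 10 to 19 with 1 section left out. The 14 cortical lists became 0 with an estimated correlation, 0 with fry, 7 in cluster 7 alone and 12 to 18 with 1 section left out, with 8 higher and 6 lower as reported, 8 and 9 without control replicate 1, and 9 and 9 without rNLS8 replicate 1. The 2 calls for Moran's I became 4 over genes in 1% of spots, 5 over genes in 50% of spots, where neither of the 2 was tested, and 5 to 60 with 1 section left out (28 higher and 32 lower without rNLS8 replicate 1). The difference in the share of cortical spots and the correlation of disease-associated microglial with neighbouring astrocyte transcripts moved by less than the spread between sections, but 8 of the 19 correlations compared moved by more without thinning, and 2 of 18 values for region shares, both of ependyma, moved by more.

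With the replicate number as a replicate block, which coincides with the labelled sex but pairs no animals, the counts were 78 for whole sections, 266 for cortex, 260 for striatum, 159 for fibre tracts, 99 for meninges and 0 for Moran's I. With crossed numbers in that replicate block they were 216, 695, 451, 132 and 161 for the 5 sets of sums.

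Values that turned sign were near 0 or from genes that did not pass, except Cplx3, on which the deep-layer spots were selected and whose difference between layers was 0.5606 without centring. In cluster 7 alone Csf1r was -0.1178, Sox9 -0.01452, Slc1a3 -0.1175, Cdh5 -0.04076 and Col1a2 -0.01976, and in cluster 3 alone Pf4 was -0.255, Hspb8 -0.04248 and Lgals3 -0.0137. Leaving out 1 section gave P2ry12 -0.08332 to 0.5142 in whole sections, cortical Col1a2 -0.05765 to 0.6567, a cortical difference of Tardbp of -0.2143 to 0.4004, and layer differences of -0.7877 to 0.04533 for P2ry12 and -0.897 to 0.1719 for Trem2. The layer difference of Trem2 was 0.6298 with thinned sums and 0.1875 at Leiden resolution 2.0, and that of Aif1 was -0.3356 with thinned sums, -0.2992 at resolution 0.5, -0.2319 without centring and -0.2352 with deep layers as all other cortical clusters. Of the values of single cortical genes, 2061 kept their direction and side of the threshold, 189 were no longer past it, 241 came past it and 9 turned.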

Other observations

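The values in this part were chosen after the data were seen, and none comes with an explanation.

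Outside the cortex, further called genes belonged to the immune and glial lists. In the striatum Usp18 (log2 fold change 3.00), Lgals3bp (2.70), Irf7 (2.55), Oasl2 (2.37), Rtp4 (2.35), C4b (1.90, uncertain against C4a), Tspo (1.71) and Ctsd (1.16) rose, and the striatal reactive astrocyte list was called with Gfap and C4b as its rising members (camera adjusted p = 1.8e-06; adjusted p = 0.495 with an estimated correlation, and 0.22 by fry). In fibre tracts Rtp4 (3 UMI in control and 104 in rNLS8, a ratio of 15.1 with a 95% counting interval of 5.02 to 74.4), Oasl2 (3.66), Bst2 (2.82), Grn (1.27), Ctsd (1.26), S100a6 (1.24), Ctss (1.22) and Vim (1.19) rose. In meninges and vessels Cxcl10 (3.48), Usp18 (2.46), Bst2 (1.85) and Ctss (1.44) rose. Neuronal genes fell there too: Rprm (-1.27) and Gria3 (-1.02) in the striatum and Calb1 (-1.10) in fibre tracts. These are edgeR calls at a Benjamini-Hochberg adjusted p under 0.05 with n = 2 sections per group.

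Cortical spots rich in transcripts of the disease-associated microglia list also had neighbours rich in transcripts of the myelin and homeostatic microglia lists in rNLS8. The Spearman correlation was 0.00787 and 0.0174 in the control sections and 0.149 and 0.328 in the rNLS8 sections for myelin. For the homeostatic list it was -0.0169 and 0.0292 against 0.217 and 0.387, and without thinning -0.0697 and 0.00686 against 0.324 and 0.538, so the difference of the group means depended on thinning (0.295 with it and 0.462 without).

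The low-count rim entered the sums of whole sections and of all other spots but was not compared as a region of its own beforehand. It had 90 called genes (38 higher and 52 lower of 10398) in clusters that the groups fill unevenly (cluster 2 with 790 and 336 spots in control and 57 and 29 in rNLS8). Its interferon list had a median log2 fold change of 1.92 (camera adjusted p = 1.5e-14; adjusted p = 0.404 with an estimated correlation).

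Some genes were read in part of the sections. Abhd6 had 32 and 212 UMI in control replicates 1 and 2 and 0 in both rNLS8 sections, and Pigv had 103 UMI in rNLS8 replicate 2 and 0 in the other sections. Zfp180 stood at 4.89 CPM in control replicate 1, 0 in control replicate 2, and 32.0 and 27.1 CPM in the rNLS8 sections. Isoc2a had 0 UMI and Phf5a 3 UMI in control replicate 2, against 249 and 238 UMI in control replicate 1.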
